A study of Mus musculus with 3 samples.

How the data were processed

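RNA of single nuclei was measured in 3 libraries of the mouse submandibular gland, a major salivary gland, with 1 library per group. Per the labels, the glands came from wild-type mice that were not irradiated, were irradiated and given saline, or were irradiated and given pilocarpine, an agonist of muscarinic acetylcholine receptors that stimulates saliva secretion. The titles give 90 days after irradiation and pilocarpine from day 30 to day 90, whereas the extraction protocol gives 93 days. The labels do not say how many mice each library holds, of which sex they were, or at what hour the glands were taken. Nuclei were released mechanically from frozen glands, stained with DAPI, sorted by flow cytometry and processed with a droplet kit for the 3' end of transcripts.

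The deposited values are counts: unique molecular identifiers (UMIs) per gene and nucleus barcode, which the authors made with Cell Ranger 7.0.1 on the mouse genome build GRCm38 and did not normalize. The labels do not state whether reads in introns were counted or which gene annotation was used. Barcodes had already been called as nuclei. The files held 32285 genes and 32511 barcodes with 90687012 UMIs in all. The lowest UMI count of a barcode was 500 in the non-irradiated library, 293 in the irradiated + saline library and 373 in the irradiated + pilocarpine library.

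Barcodes were kept with at least 500 genes and at most 5% mitochondrial UMIs. The gene minimum removed 1425, 1536 and 1911 barcodes of the non-irradiated, irradiated + saline and irradiated + pilocarpine libraries, and the mitochondrial maximum was exceeded by 3, 13 and 10. Doublets were called per library with scrublet, as run by scanpy 1.11.5 with an expected rate of 6%. It called 6, 1 and 0 barcodes, which were removed. These are under 0.5% of each library, so the caller did not work here and the doublets it missed stayed in the data. For that reason an alternative also removed the nuclei with the highest doublet scores, 8.37%, 8.26% and 8.64% of those used in the same order of libraries. A total of 27626 nuclei with 88082072 UMIs were used.

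All nuclei were clustered together on 3000 variable genes with 30 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2), without integration of the libraries. Every gene of the lists compared was left out of the variable genes, as were mitochondrial, ribosomal, immunoglobulin and sex-linked genes. A cluster was called like a cell type when at least 3 markers of that type, fixed before the data were examined, had a median level of at least 0.65 of the highest cluster's level. The 10 leading genes by fold also had to hold no more markers of another type. The level of 0.65 was set after seeing the data, from 0.75 at first, because acinar clusters in other clusterings fell between the 2 levels. Class shares with 0.75 in the clustering used were identical. Cluster names were rebuilt here and may differ from those of the study.

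UMIs were summed over the nuclei of a class in each library and expressed as CPM, a rate over all UMIs of those nuclei. Shares have exact Clopper-Pearson 95% intervals, and differences of shares have Newcombe intervals. Ratios of CPM have exact conditional binomial intervals, and CPM values have exact Poisson intervals. For each gene list, the log2 ratio of CPM + 1 was taken over members with at least 10 UMIs in both libraries together, and the median was placed by percentile among 10000 random lists of the same size. Each random member was drawn from the 50 genes nearest in mean CPM. The counting interval of a list's median comes from 200 Poisson draws. Classes with at least 300 nuclei in each library were compared, which were the acinar-like, granular or striated duct-like, fibroblast-like and myoepithelial-like nuclei. There were no replicate libraries, so no test between groups was run, and every interval covers counting error only. No paired analysis was possible because each group has 1 library.

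The named genes followed a rule fixed before the data were examined. In acinar-like and duct-like nuclei, these are the 4 genes most above and the 4 most below in each comparison, ranked by the interval bound nearest to no change. They needed at least 50 UMIs, and a CPM at least that of all other nuclei in the higher library. Markers of the class, mitochondrial, ribosomal, immunoglobulin and sex-linked genes and predicted gene names were left out. The rule adds the 2 members with the largest ratio of each list described, and Chrm3, Chrm1, Aqp5, Atp2a2, Cdkn1a and Egf in every case. Results on 2 further genes that the rule takes are not reported here. Which lists to describe with 2 members was decided after seeing their medians. Gene positions on GRCm38 come from a GENCODE annotation matched by gene ID, in which all 97 genes looked up were found.

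The opposite change of genes was measured across genes as Spearman's rho between the log2 ratios of both comparisons. The irradiated + saline nuclei were divided at random in 20 draws, so that each comparison used its own part. Libraries with no change between groups were simulated for reference. The intervals were also run on simulated Poisson counts without variation between nuclei or libraries. That is the model for which they are exact, so the result checks the computation only. The intervals covered the true ratio in 95.4% to 96.3% of unchanged genes. They excluded no change for 95.5% and 94.0% of acinar genes with a simulated fold of 2. In duct-like nuclei these values were 92.5% and 82.1%.

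Alternatives fixed before the data were examined were a minimum of 1000 or 200 genes, at most 1% mitochondrial UMIs, doublets kept, each library clustered alone, all variable genes, and resolutions of 0.5 and 2. For list medians and genes they were TMM factors (edgeR 4.0.16), CPM without the 50 most abundant genes, a mean over nuclei, thinning of each nucleus to equal UMIs, subtraction of free RNA, a minimum of 50 UMIs and a pseudocount of 10 CPM. The thinned depth of 800 UMIs was chosen after seeing the data. Free RNA was taken per gene as the lowest CPM among endothelial-like, fibroblast-like and immune-like nuclei of the same library. Those nuclei may express a gene themselves, so the amount subtracted can hold their own RNA as well as free RNA. Values after subtraction therefore show how a result depends on this step and are not corrected values. Fibroblast-like nuclei are among these classes, so a gene lowest in them is set to 0 there. A member left at 0 in 1 library has a log2 ratio that depends on the pseudocount, so medians after subtraction are not exact. Alternatives chosen after seeing the data were removal of the highest doublet scores, cluster 11 counted as acinar-like, shares of named clusters alone, the naming level of 0.75, and equal weights for the acinar-like clusters 0 to 3. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.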

Results

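The series measured RNA in single nuclei of the mouse submandibular gland, to follow cell identities and signalling pathways after irradiation and after irradiation with pilocarpine. There were 3 groups with 1 library each and no replicates, so the differences below describe these libraries, and a difference between groups cannot be separated from a difference between libraries. The non-irradiated library held 12062 barcodes and 26417958 UMIs, the irradiated + saline library 10161 barcodes and 29946943 UMIs, and the irradiated + pilocarpine library 10288 barcodes and 34322111 UMIs. After filtering, 10629, 8621 and 8376 nuclei remained in that order, with a median of 1536, 2113 and 2048 UMIs per nucleus. The nuclei formed 22 clusters. Clusters 7, 8, 11, 12, 17 and 19 stayed unnamed and held 15.7% of the non-irradiated, 14.2% of the irradiated + saline and 10.5% of the irradiated + pilocarpine nuclei. RNA of acinar cells was also found in other nuclei. Mucl2, which encodes a secreted acinar product, reached 47580, 57373 and 54774 CPM in acinar-like nuclei and 38215, 38365 and 47260 CPM in endothelial-like nuclei of the same libraries. Such levels differed between classes. In the irradiated + saline library Mucl2 stood at 26935 CPM in fibroblast-like and 17085 CPM in duct-like nuclei. Egf, a product of duct cells, stood there at 2468 CPM in endothelial-like and 240 CPM in fibroblast-like nuclei. Free RNA and doublets left in the data could each bring such RNA, and which of them did was not tested.

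The comparison of irradiated + saline with non-irradiated glands asks how the gland differs months after irradiation. The label of the non-irradiated library is no treatment and names no saline. Effects of irradiation and of saline therefore cannot be told apart in this comparison. Acinar-like nuclei, the saliva-producing cells, made up 61.5% of non-irradiated nuclei (60.6% to 62.4%) and 42.2% of irradiated + saline nuclei (41.2% to 43.3%). That is a difference of -19.3 percentage points (-20.7 to -17.9). Granular or striated duct-like nuclei, of the ducts that modify saliva and secrete growth factors, made up 6.11% and 19.2%, a difference of 13.1 points (12.1 to 14.0). Ionocyte-like nuclei made up 2.67% and 5.28%. Macrophage-like nuclei made up 1.04% and 2.96%, and T or NK-like nuclei 0.489% and 1.10%. Fibroblast-like nuclei made up 5.64% and 6.62%, myoepithelial-like nuclei 3.38% and 4.61%, and endothelial-like nuclei 2.31% and 2.41%. Pericyte or smooth muscle-like nuclei made up 0.235% and 0.510%, lymphatic endothelial-like nuclei 0.0847% and 0.290%, and Schwann-like nuclei 0.499% and 0.568%. Intervals cover counting error only, and nuclei were sorted before sequencing, so the shares are of sorted nuclei. The acinar difference was -12.1 points with a minimum of 1000 genes and -30.4 points with each library clustered alone. With a minimum of 1000 genes, the difference was -0.0706 points for endothelial-like (and 0.412 with the highest doublet scores removed), -0.00937 for lymphatic endothelial-like and 0.406 for myoepithelial-like nuclei. With each library clustered alone it was 2.90 for macrophage-like, 1.10 for T or NK-like and 0.0133 for Schwann-like nuclei, and with a minimum of 200 genes 1.70 for ionocyte-like and 0.385 for Schwann-like nuclei.

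**Figure D1:**
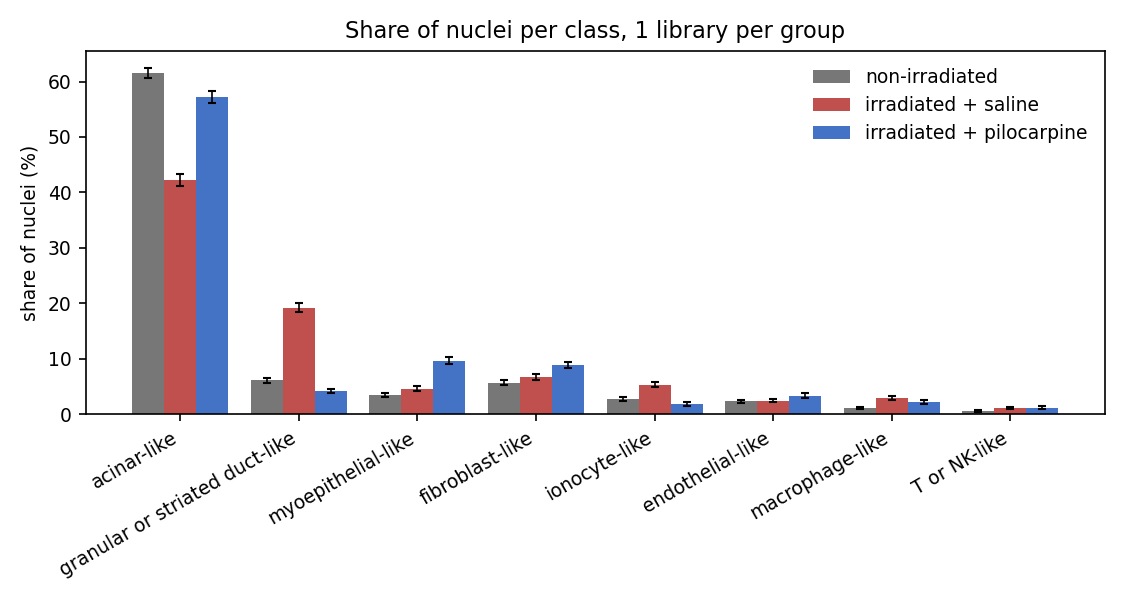
Share of nuclei per class in percent of all nuclei used, 1 bar per library, with exact Clopper-Pearson 95% intervals that cover counting error only. Acinar-like nuclei made up 61.5% of non-irradiated, 42.2% of irradiated + saline and 57.3% of irradiated + pilocarpine nuclei, and granular or striated duct-like nuclei made up 6.11%, 19.2% and 4.15%.

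Within acinar-like nuclei, p53 targets, interferon response genes, genes of the unfolded protein response and immediate early genes were higher in the irradiated + saline library than in the non-irradiated library. The median log2 ratio of p53 targets and DNA damage genes was 0.79, at percentile 100 of the random lists, with 24 of 29 measured members higher. Gdf15, a stress-induced cytokine, was 7.71 times as high (3.82 to 17.6), and the p53-induced noncoding RNA Pvt1 was 3.92 times as high (3.40 to 4.53). The interferon response had a median of 0.46 at percentile 100, with 21 of 24 members higher. Ifi27l2a was 3.55 times as high (3.08 to 4.10) and Usp18, a regulator of interferon signalling, 3.05 times (2.58 to 3.63), although Usp18 was lower, at a log2 ratio of -1.30, once free RNA was subtracted. The unfolded protein response and secretory pathway had a median of 0.29 at percentile 100, with 28 of 29 members higher. Among them were the stress-induced transcription factor gene Ddit3, 2.18 times as high (1.82 to 2.63), and the chaperone gene Dnajb9, 2.15 times (1.78 to 2.61). Immediate early and stress genes had a median of 0.57 at percentile 100, with 18 of 22 members higher, such as Ier3 at 6.15 times (4.13 to 9.46) and Jun at 3.65 times (2.87 to 4.67). A pseudocount of 10 CPM gave medians of 0.39 for p53 targets and 0.22 for immediate early genes, and equal weights for clusters 0 to 3 gave 0.52 for p53 targets. Subtraction of free RNA gave a median of 0.47 for the unfolded protein response and 0 for the interferon response, where 12 of 24 members were at 0 in both libraries and 9 of the other 12 were lower. Most non-irradiated acinar-like nuclei lay in clusters 0 (49.1%) and 3 (38.8%), and most irradiated + saline ones in clusters 1 (51.7%) and 2 (31.3%). Clusters 0, 3, 1 and 2 had medians of 1109, 2364.5, 3662 and 1756 UMIs per nucleus. The median of acinar-like nuclei was 1524 UMIs in the non-irradiated and 2496.5 in the irradiated + saline library. The acinar share difference and the acinar lists therefore compare nuclei of unlike depth.

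Lists of saliva secretion and energy supply had smaller medians, except for the mitochondrially encoded genes. Muscarinic and calcium signalling genes had a median log2 ratio of -0.17 at percentile 0.090, with 28 of 43 members lower. In this list the plasma membrane calcium pump gene Atp2b4 was 3.65 times lower (2.52 to 5.38) and the Golgi calcium pump gene Atp2c2 was 19.8 times as high (5.09 to 169), with 37 UMIs against 2. After subtraction of free RNA this median was 0, with 17 members higher, 15 lower and 11 at 0 in both libraries. Nuclear genes of oxidative phosphorylation had a median of 0.040 at percentile 96.1, with 45 of 76 members higher. It was -0.044 with free RNA subtracted, -0.0012 with each library clustered alone and 0.11 with equal weights for clusters 0 to 3. Uqcrq of complex III was 1.47 times as high (1.25 to 1.73) and Atp5g1 of the ATP synthase 1.47 times (1.22 to 1.79). The 13 mitochondrially encoded genes had a median of 0.31 at percentile 99.96, with mt-Cytb at 1.71 times (1.43 to 2.05) and mt-Co2 at 1.61 times (1.34 to 1.95). Mitochondrially encoded RNA made up a mean of 0.0412% of the UMIs of a barcode in the non-irradiated and 0.0855% in the irradiated + saline library. The list's median was 0.10 with at most 1% mitochondrial UMIs, 1.10 with equal weights for clusters 0 to 3 and 0 with free RNA subtracted, where 6 members were at 0 in both libraries, 2 higher and 5 lower. Acinar secretory products had a median of 0.14 at percentile 98.0, with 8 of 13 members higher, 0.60 with free RNA subtracted and 0.079 with a pseudocount of 10 CPM. Bpifa2, a secreted acinar protein, was 49.8 times as high (34.5 to 74.7), and Pigr, which carries immunoglobulin A into saliva, was 3.55 times lower (2.97 to 4.26). Secretion channels and transporters had a median of -0.011 at percentile 66.6, with Cldn3 at 1.88 times as high (1.56 to 2.28) and Rab27b 1.40 times lower (1.34 to 1.46). This median was 0.26 with free RNA subtracted.

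Extracellular matrix and fibrosis genes had the lowest median in acinar-like nuclei, -0.49 at percentile 0, with 23 of 31 members lower. Col1a2 was 4.002 times lower (2.05 to 8.56) and Col5a2 2.90 times lower (1.77 to 4.92). Their acinar levels were small beside other nuclei: Col1a2 stood at 3.93 and 0.981 CPM in non-irradiated and irradiated + saline acinar-like nuclei, and at 60.3 and 43.3 CPM in all other nuclei. The matrix median was -0.12 with nuclei thinned to 800 UMIs, -0.0045 with equal weights for clusters 0 to 3 and 0 with free RNA subtracted. Of its members 8 were then higher and 14 lower, and Col1a2 was higher, at a log2 ratio of 0.99. Neurotrophic factors and axon guidance genes had a median of -0.27 at percentile 0.51, with 14 of 17 members lower. Sema3a, a repulsive axon guidance cue, was 3.15 times lower (1.94 to 5.33), and the beta-adrenergic receptor gene Adrb1 was 2.10 times as high (1.99 to 2.22). This median was -0.49 with each library clustered alone, -0.070 with nuclei thinned to 800 UMIs and 0 with free RNA subtracted, with 3 members higher and 7 lower. ErbB ligands and receptors had a median of -0.27, progenitor and duct plasticity genes -0.15, and mitochondrial biogenesis and energy sensing genes -0.12. Senescence and secreted inflammatory factors had a median of -0.092, fatty acid oxidation genes -0.076, glycolysis genes -0.069, and genes of the TCA cycle and pyruvate entry -0.016. Granular tubule products had a median of 0.23, proliferation genes 0.21 and the oxidative stress response 0.048. The medians of granular tubule products and proliferation genes were -0.20 and -0.028 with each library clustered alone, 0.57 for the former with equal weights for clusters 0 to 3 and 0.81 for the latter with all variable genes. Subtraction of free RNA moved the medians to 0.12 for ErbB genes, 0.032 for progenitor genes, -0.060 for mitochondrial biogenesis, -0.43 for glycolysis, 0.11 for the TCA cycle, -0.14 for proliferation and 0.43 for oxidative stress. They were 0 for senescence factors (3 members higher, 4 lower), fatty acid oxidation (9 and 7) and granular tubule products (1 and 4), and the median of senescence factors was 0.093 with a mean over nuclei.

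Of single genes in acinar-like nuclei, the major urinary protein gene Mup5 was 9.19 times as high in the irradiated + saline library (8.55 to 9.89), at 627 against 68.2 CPM. Sel1l3 was 17.4 times as high (8.17 to 44.2), the olfactory receptor gene Olfr1395 12.6 times (7.18 to 24.3) and the GTPase regulator gene Chn2 7.19 times (6.33 to 8.18). Rnf212b gave 343 UMIs in the non-irradiated library, 1 in the irradiated + saline library (0.00311 times its CPM, 7.86e-05 to 0.0175) and 2 in the irradiated + pilocarpine library. Card14 was 28.8 times lower with irradiation and saline (10.97 to 107), Extl1 9.19 times (5.85 to 15.2) and the complement protease gene Masp2 5.26 times (3.90 to 7.21). Mup5 was among the 10 leading genes of clusters 1 and 2, and Rnf212b of cluster 3. The muscarinic receptor gene Chrm3 (chromosome 13, 9875486 to 10360847) stood at 3974 and 3794 CPM, and Chrm1 (chromosome 19, 8663789 to 8683587) at 11.1 and 14.3 CPM. Chrm3 stood at 2473 and 1732 CPM in endothelial-like and at 1485 and 632 CPM in fibroblast-like nuclei. Its acinar log2 ratio was 0.35 with free RNA subtracted. The water channel gene Aqp5 (chromosome 15, 99590782 to 99594829) stood at 216 and 231 CPM, and the calcium pump gene Atp2a2 (chromosome 5, 122453513 to 122502225) at 527 and 468 CPM. The growth factor gene Egf, a product of duct cells, stood at 352 and 302 CPM. The cell cycle inhibitor gene Cdkn1a gave 1 and 16 UMIs, 17.1 times as high (2.65 to 716), and its log2 ratio was -0.12 with free RNA subtracted.

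**Figure D2:**
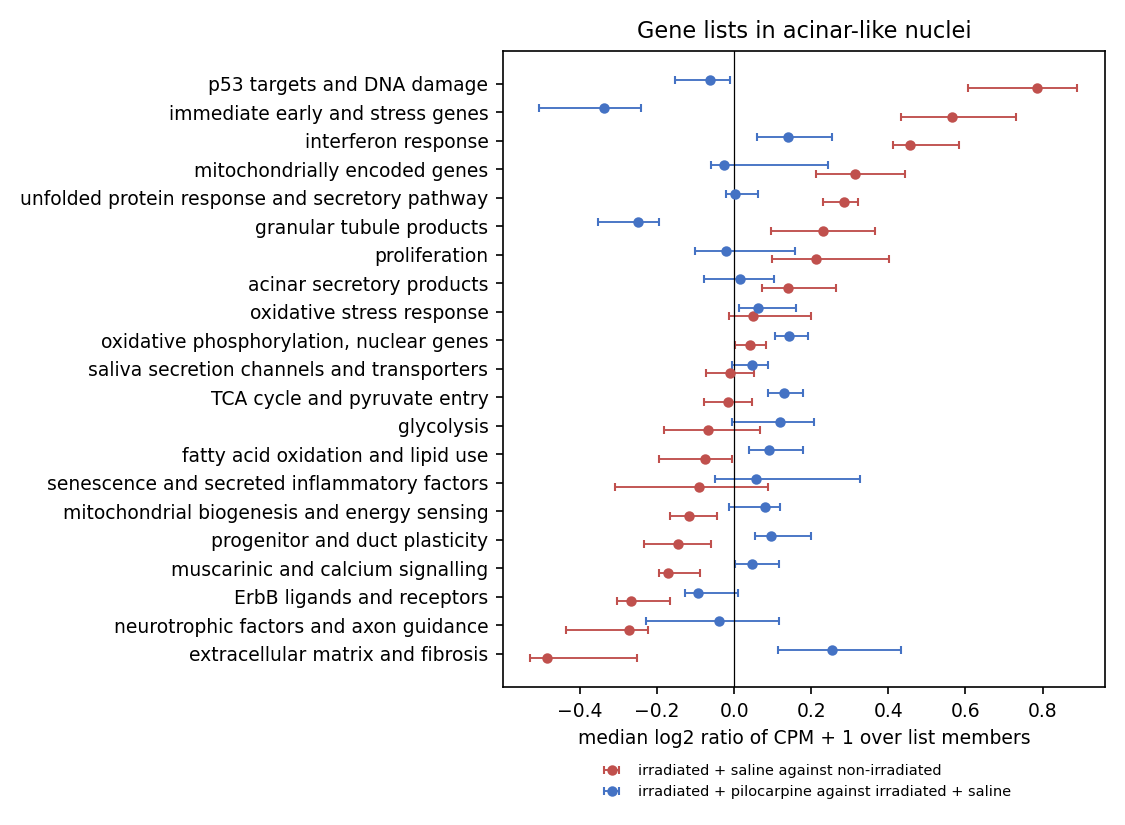
Median log2 ratio of CPM + 1 over the measured members of each gene list in acinar-like nuclei, for irradiated + saline against non-irradiated (red) and irradiated + pilocarpine against irradiated + saline (blue). Horizontal bars are 95% intervals from Poisson draws and cover counting error only. The p53 list stands at 0.79 and -0.064, and immediate early and stress genes at 0.57 and -0.34.

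In granular or striated duct-like nuclei, which held 888585 UMIs in the non-irradiated and 3169135 in the irradiated + saline library, granular tubule products and interferon response genes were higher in the latter. Granular tubule products had a median log2 ratio of 0.83 at percentile 100, and 17 of 17 members were higher. The kallikrein genes Klk1b24 and Klk1b11 were 3.43 times (2.18 to 5.72) and 2.31 times as high (2.05 to 2.61), and Egf stood at 7294 against 5092 CPM. The interferon response had a median of 1.13 at percentile 100, with 18 of 20 members higher, among them Trim30a at 22.7 times (3.96 to 908), with 81 UMIs against 1, and Rtp4 at 16.0 times (2.76 to 642), with 57 against 1. p53 targets and DNA damage genes had a median of 0.32 at percentile 99.8, with 15 of 25 members higher. Perp, a p53-induced membrane protein gene, was 2.90 times as high (1.26 to 8.20), the chloride channel family gene Ano3 gave 63 UMIs against 0, and Cdkn1a gave 18 UMIs against 0, with lower bounds of the CPM ratio of 4.65 and 1.23. Both medians were 0 with free RNA subtracted: 7 of 20 interferon members were at 0 in both libraries, 5 were higher and 8 lower, and of the p53 targets 12 were higher and 11 lower. The p53 median was 0.14 with a minimum of 200 genes. Of single genes, the glutamate receptor gene Gria3 was 3.11 times as high (2.70 to 3.60), the carboxylesterase gene Ces1d 3.01 times (2.40 to 3.82) and the adenylate cyclase gene Adcy2 2.71 times (2.37 to 3.11). Igsf21 was 7.23 times lower (5.75 to 9.13), Grik1 3.18 times (2.03 to 4.95) and Mrpl45 2.96 times (1.82 to 4.78). Acinar secretory products in duct-like nuclei had a median of -1.10, with Pigr 10.7 times lower (4.38 to 29.8) and Oit1 4.25 times lower (3.38 to 5.35). It was 0 with free RNA subtracted, which left 7 of 11 members at 0 in both libraries, 1 higher and 3 lower. Chrm3 stood at 1837 and 1694 CPM, below the 2473 and 1732 CPM of endothelial-like nuclei and above the 1485 and 632 CPM of fibroblast-like nuclei. Its log2 ratio was 1.59 with free RNA subtracted. Aqp5 stood at 54.0 and 16.1 CPM and Atp2a2 at 262 and 239 CPM. Chrm1 gave 0 and 8 UMIs, and the lower bound of its ratio, 0.479, lay below 1, so a difference was not detectable at this depth.

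In fibroblast-like nuclei the interferon response had a median log2 ratio of 1.02 between these libraries, with 27 of 28 members higher. The antiviral genes Oas2 and Ifit3 were 4.69 times (2.93 to 7.85) and 5.70 times as high (2.41 to 16.4). p53 targets and DNA damage genes had a median of 0.70, with 20 of 24 members higher, including Eda2r at 2.39 times (1.30 to 4.63) and Ano3 at 5.42 times (1.23 to 49.5), with 13 UMIs against 2. These medians were 0.52 and 0.28 with free RNA subtracted, and Eda2r was lower, at a log2 ratio of -0.39. Fibroblast-like nuclei are among the classes from which free RNA was taken, so a gene lowest in them is set to 0 there. The p53 median was 0.13 with nuclei thinned to 800 UMIs. Extracellular matrix and fibrosis genes had a median of 0.28 at percentile 98.9, with 23 of 34 members higher. The matricellular gene Ccn2 was 6.50 times as high (2.56 to 21.1) and the metalloproteinase inhibitor gene Timp3 2.87 times (2.43 to 3.41). The matrix median was 0.12 with free RNA subtracted. In myoepithelial-like nuclei, the contractile cells around acini, the interferon response had a median of 0.59, with 17 of 20 members higher, and p53 targets 0.38, with 17 of 21 higher. Oasl2 was 3.97 times (2.40 to 6.91), Ifi27l2a 3.50 times (1.88 to 6.99), Plk2 2.16 times (1.36 to 3.51) and Aen 3.60 times as high (1.32 to 12.2). The myoepithelial interferon median was 0.31 with nuclei thinned to 800 UMIs and 0 with free RNA subtracted (5 members higher, 7 lower), and the p53 median 0.68 when thinned and 0.24 over members with at least 50 UMIs. Acinar secretory products had medians of -0.76 in fibroblast-like and -0.73 in myoepithelial-like nuclei. With free RNA subtracted both were 0, with 1 member higher and 3 lower in the first and 3 higher and 2 lower in the second. Over all nuclei, granular tubule products had a median of 1.32 and acinar secretory products of -0.086.

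The comparison of irradiated + pilocarpine with irradiated + saline glands asks how the irradiated gland differs after a muscarinic agonist. Acinar-like nuclei made up 57.3% (56.2% to 58.3%) with pilocarpine and 42.2% with saline, a difference of 15.03 percentage points (13.5 to 16.5). Granular or striated duct-like nuclei made up 4.15% with pilocarpine and 19.2% with saline, a difference of -15.02 points (-16.0 to -14.1). Myoepithelial-like nuclei made up 9.66% against 4.61%, and fibroblast-like nuclei 8.85% against 6.62%. Ionocyte-like nuclei made up 1.78% against 5.28%, and macrophage-like nuclei 2.15% against 2.96%. Endothelial-like nuclei made up 3.33% against 2.41%, T or NK-like nuclei 1.11% against 1.10%, and Schwann-like nuclei 0.740% against 0.568%. Pericyte or smooth muscle-like nuclei made up 0.334% against 0.510%, and lymphatic endothelial-like nuclei 0.0955% against 0.290%. Set against the non-irradiated library, the acinar-like share with pilocarpine differed by -4.24 points (-5.65 to -2.83) and the duct-like share by -1.95 points (-2.57 to -1.32). The acinar difference from the non-irradiated library ranged from -12.8 points with each library clustered alone to 2.65 points with a minimum of 1000 genes. With that minimum, pilocarpine minus saline was 1.22 points for fibroblast-like, 0.0203 for endothelial-like, -0.0507 for lymphatic endothelial-like and -0.147 for Schwann-like nuclei. It ranged from -0.0431 to 0.186 for T or NK-like nuclei, and was -0.321 for macrophage-like nuclei at resolution 0.5 and -2.27 for ionocyte-like nuclei at resolution 2.

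Within acinar-like nuclei, the irradiated + pilocarpine library had lower immediate early and stress genes, and higher nuclear genes of oxidative phosphorylation and of the TCA cycle, than the irradiated + saline library. Immediate early and stress genes had a median log2 ratio of -0.34 at percentile 0, with 21 of 22 members lower. The phosphatase gene Dusp1 was 5.28 times lower (4.02 to 7.04) and the transcription factor gene Fos 5.16 times lower (2.09 to 15.3). This median was -0.14 with a pseudocount of 10 CPM and -0.82 with free RNA subtracted. Oxidative phosphorylation genes had a median of 0.14 at percentile 99.7, with 60 of 76 members higher. Ndufb11 of complex I was 1.91 times as high (1.43 to 2.59) and Atp5j2 of the ATP synthase 1.44 times (1.23 to 1.68). This median was 0.093 with TMM factors and 0.52 with free RNA subtracted. The TCA cycle and pyruvate entry list had a median of 0.13 at percentile 99.3, with 23 of 30 members higher, such as Idh3b at 1.34 times (1.23 to 1.46) and Pdk1 at 1.29 times (1.13 to 1.47). With free RNA subtracted, the list's median was -0.021 and the log2 ratio of Pdk1 was -0.14. Mitochondrially encoded genes had a median of -0.026, which was 0.18 with a minimum of 200 genes and -0.34 with equal weights for clusters 0 to 3. Most acinar-like nuclei of the irradiated + pilocarpine library lay in clusters 2 (37.9%), 1 (35.1%) and 0 (20.1%).

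Lists of secretion and calcium signalling were close between these libraries before free RNA was subtracted. Muscarinic and calcium signalling genes had a median of 0.047 at percentile 71.6, with 28 of 43 members higher. It was -0.0077 with TMM factors and 0 with free RNA subtracted, with 13 members higher, 17 lower and 13 at 0 in both libraries. Atp2b4 was 2.29 times as high (1.55 to 3.44) and the calcineurin gene Ppp3ca 1.16 times lower (1.12 to 1.198). Acinar secretory products had a median of 0.015 at percentile 76.0, and -0.31 with free RNA subtracted, with 2 members higher and 10 lower. Bpifa2 was 3.55 times lower (3.18 to 3.96) and Pigr 1.73 times as high (1.42 to 2.11). Secretion channels and transporters had a median of 0.047 at percentile 68.7, with Cldn10 at 1.29 times as high (1.25 to 1.32) and Kcnma1 1.10 times lower (1.09 to 1.11). This median was -0.0069 with TMM factors and -0.19 with free RNA subtracted, with 4 members higher and 16 lower. p53 targets and DNA damage genes had a median of -0.064 at percentile 0.50, with 20 of 29 members lower, Psrc1 2.16 times lower (1.30 to 3.65) and Btg2 1.46 times lower (1.21 to 1.77). This median was 0.0049 with equal weights for clusters 0 to 3 and -0.23 with free RNA subtracted. The interferon response had a median of 0.14 at percentile 95.4, with 17 of 25 members higher, Gbp2 at 5.78 times (2.73 to 14.1) and Gbp3 at 4.19 times (2.09 to 9.28). It was 0.25 with a minimum of 1000 genes, 0.045 with equal weights for clusters 0 to 3 and 0 with free RNA subtracted, where 12 of 25 members were at 0 in both libraries, 9 higher and 4 lower. Extracellular matrix and fibrosis genes had a median of 0.25 at percentile 99.5, with Acta2 at 2.20 times as high (1.34 to 3.74) and Ccn1 3.51 times lower (1.96 to 6.61), and the median was 0.40 with a minimum of 200 genes, 0.064 with a pseudocount of 10 CPM and 0 with free RNA subtracted, where 13 of 31 members were at 0 in both libraries, 7 higher and 11 lower. Acta2 is a marker of myoepithelial cells, whose share was also higher with pilocarpine, and stood at 116 CPM in all other nuclei against 4.51 CPM in acinar-like nuclei.

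Granular tubule products in acinar-like nuclei had a median of -0.25 with 15 of 17 members lower, beside the lower duct-like share. Klk1b21 was 1.60 times lower (1.26 to 2.04). Endothelial-like nuclei held more Klk1b21 than acinar-like nuclei, at 265 against 14.8 CPM with saline and 36.0 against 9.26 CPM with pilocarpine. With each library clustered alone the list's median was -0.093 and the log2 ratio of Klk1b21 was 0.19, and with equal weights for clusters 0 to 3 the median was -0.48. After subtraction of free RNA the median was 0, with 12 of 17 members at 0 in both libraries, 4 higher and 1 lower. Of the other lists, glycolysis genes had a median of 0.12, progenitor and duct plasticity genes 0.097, fatty acid oxidation genes 0.090, and mitochondrial biogenesis and energy sensing genes 0.081. The oxidative stress response had a median of 0.062, senescence and secreted inflammatory factors 0.056, the unfolded protein response 0.0033, proliferation genes -0.022, neurotrophic factors -0.038, and ErbB ligands and receptors -0.093. With free RNA subtracted, the medians were -0.14 for progenitor genes, -0.16 for oxidative stress, -0.26 for mitochondrial biogenesis, -0.33 for the unfolded protein response, -0.51 for ErbB genes and 0.043 for glycolysis. They were 0 for fatty acid oxidation (9 members higher, 8 lower), senescence factors (2 and 4), proliferation (14 and 10) and neurotrophic factors (3 and 5). The median of neurotrophic factors was 0.23 with each library clustered alone and -0.31 with equal weights for clusters 0 to 3. That of proliferation was 0.14 with a minimum of 200 genes and -0.32 with all variable genes, and that of senescence factors 0.15 with a minimum of 1000 genes and -0.077 with equal weights.

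Of single genes in acinar-like nuclei, the MHC class I gene H2-K1 was 2.48 times as high with pilocarpine (2.35 to 2.61), at 424 against 171 CPM. The riboflavin transporter gene Slc52a2 was 2.58 times as high (1.55 to 4.45), the phospholipase C gene Plcd4 2.98 times (1.54 to 6.23) and the GTPase regulator gene Rap1gap 1.54 times (1.49 to 1.59). Rap1gap was among the 10 leading genes of cluster 0. Lingo2 was 8.35 times lower (4.76 to 15.8), the phosphatase gene Dusp5 2.59 times (2.24 to 3.003) and the insulin signalling gene Irs2 2.56 times (2.24 to 2.92). Chrm3 stood at 3681 CPM with pilocarpine and 3794 CPM with saline, and Chrm1 at 12.1 and 14.3 CPM. Aqp5 stood at 264 and 231 CPM and Atp2a2 at 528 and 468 CPM. With free RNA subtracted their log2 ratios turned to -0.070 and -0.16. Egf stood at 288 and 302 CPM, and its log2 ratio was 0.78 with free RNA subtracted and 0.23 with each library clustered alone. Cdkn1a gave 18 and 16 UMIs, a ratio of 0.981 (0.472 to 2.06), so a difference was not detectable at this depth.

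In granular or striated duct-like nuclei, of which the irradiated + pilocarpine library held 348 with 502330 UMIs, granular tubule products were lower and nuclear genes of oxidative phosphorylation higher with pilocarpine than with saline. Granular tubule products had a median log2 ratio of -0.65 at percentile 0, with 15 of 17 members lower. Egf was 1.85 times lower (1.76 to 1.93), at 3950 against 7294 CPM. Oxidative phosphorylation genes had a median of 0.35 at percentile 100, with 61 of 76 members higher, Uqcr11 at 3.56 times (2.01 to 6.15) and Ndufa2 at 3.004 times (1.26 to 6.67). Mitochondrially encoded genes had a median of 1.12, with 11 of 12 members higher, such as mt-Co1 at 2.48 times (2.06 to 2.96) and mt-Co3 at 2.36 times (1.91 to 2.91). The mean mitochondrial share of UMIs over all barcodes, a sign of RNA from outside the nucleus, was 0.0412% in the non-irradiated, 0.0855% in the irradiated + saline and 0.102% in the irradiated + pilocarpine library. With free RNA subtracted, the mitochondrially encoded genes had a median of 3.38, with 11 members higher and 1 lower. As 6 of 12 members were then at 0 in 1 of the libraries, this value depends on the pseudocount. The oxidative phosphorylation median was 0.67 with free RNA subtracted and 0.23 with each library clustered alone. The oxidase gene Duox2 was 8.54 times as high (5.36 to 13.7). The transcription factor gene Maf was 3.09 times lower (2.07 to 4.82) and Luzp4 2.67 times (1.82 to 4.06), while the peptide transporter gene Slc15a1 and Klhdc3 each gave 1 UMI against 60, a CPM ratio of 0.105 (0.00262 to 0.609). Acinar secretory products had a median of 1.25 in duct-like nuclei, with Car6 at 3.47 times as high (3.25 to 3.71), and of 0 with free RNA subtracted, which left 6 of 10 members at 0 in both libraries, 3 higher and 1 lower. Mucl2 and Scgb1b27 were 3.51 times (3.46 to 3.56) and 3.29 times as high (3.16 to 3.42). Mucl2 then stood at 59901 CPM in duct-like, 54774 CPM in acinar-like and 47260 CPM in endothelial-like nuclei with pilocarpine. The duct-like level of this acinar product was thus above the acinar-like one, so the duct-like values may hold RNA of acinar cells. Chrm3 stood at 1981 against 1694 CPM, with a log2 ratio of -0.47 once free RNA was subtracted, Aqp5 at 41.8 against 16.1 CPM and Atp2a2 at 263 against 239 CPM. Chrm1 and Cdkn1a gave 1 UMI each, against 8 and 18, at CPM ratios of 0.789 (0.0178 to 5.88) and 0.350 (0.00841 to 2.22), so a difference was not detectable at this depth.

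In fibroblast-like nuclei, extracellular matrix and fibrosis genes had a median of -0.18 at percentile 2.62 with pilocarpine against saline, with 23 of 34 members lower. Timp3 was 1.59 times lower (1.41 to 1.79) and the proteoglycan gene Lum 1.70 times lower (1.33 to 2.17). The median was -0.054 at resolution 2 and 0.015 with the highest doublet scores removed, an alternative chosen after seeing the data. Acinar secretory products had a median of 1.00 in fibroblast-like and 1.00 in myoepithelial-like nuclei. With free RNA subtracted both were 0, with 4 members higher and 1 lower in the first and 2 higher and 3 lower in the second. Over all nuclei, granular tubule products had a median of -1.48 and acinar secretory products of 0.20.

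Against the non-irradiated library, acinar-like nuclei of the irradiated + pilocarpine library had medians of 0.76 for the interferon response, with 23 of 25 members higher, 0.65 for p53 targets, 0.29 for the unfolded protein response and 0.17 for oxidative phosphorylation. Muscarinic and calcium signalling genes had a median of -0.12 and acinar secretory products 0.059. The interferon medians were 0.99 in duct-like, 0.84 in fibroblast-like and 1.08 in myoepithelial-like nuclei, and those of p53 targets -0.012, 0.46 and 0.33. With free RNA subtracted, acinar medians were 0 for the interferon response (8 members higher, 9 lower), calcium signalling (15 and 18) and secretory products (6 and 6), 0.19 for p53 targets and 0.55 for oxidative phosphorylation. The interferon medians were then 0 in duct-like (7 and 3), 0.53 in fibroblast-like (20 and 7) and 0 in myoepithelial-like nuclei (12 and 8), and those of p53 targets -0.24, 0.17 and -0.023. A pseudocount of 10 CPM gave acinar medians of 0.36 for the interferon response and 0.28 for p53 targets, and the fibroblast p53 median was 0.13 with nuclei thinned to 800 UMIs. The duct p53 median ranged from -0.28 to 0.10, and the acinar secretory median was 0.27 when thinned. Across 12978 genes in acinar-like nuclei, the log2 ratios of both comparisons, with the irradiated + saline nuclei divided between them, had a Spearman's rho of -0.146 (-0.158 to -0.135 over 20 draws). In simulated libraries without change it was 0.0047. These were drawn with counting error only, so they do not show what differences between single libraries would give. Genes are not independent replicates, and dividing the nuclei removes shared counting error but not what is particular to the irradiated + saline library.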

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

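The library, not the nucleus, is the unit that would need replicates, so no alternative says how far glands of a group differ. The alternatives were run on 26 differences of shares, 72 list medians and 118 gene ratios, and each result is counted once per alternative. A value is counted as reversed if its counting interval excluded 0 and its sign changed, which held 2, 14 and 13 times. Other values lay outside that interval 42, 158 and 315 times and within it 268, 1172 and 1746 times, sign changes of values whose interval included 0 among them. The acinar-like share, irradiated + saline minus non-irradiated, ranged from -30.4 to -12.1 points, and irradiated + pilocarpine minus irradiated + saline from 13.9 to 18.0 points, so both kept their direction under the alternatives run. The cause of the changes below was not tested. Subtraction of free RNA leaves 12 of 24 interferon and 12 of 17 granular tubule members at 0 in both acinar libraries of irradiated + saline against non-irradiated, so those medians of 0 show no direction. Of 43 calcium members 11 are then at 0 in both, 17 higher and 15 lower. Thinning to 800 UMIs kept 6054 of 6538, 3561 of 3642 and 4693 of 4797 acinar-like nuclei.

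In the following, the first comparison is irradiated + saline against non-irradiated and the second irradiated + pilocarpine against irradiated + saline. With a minimum of 1000 genes, the acinar share difference of the first was -12.1 points, the duct share differences were 10.98 and -12.5, the oxidative phosphorylation median of the first was 0.087 and rho was -0.130. The acinar share with pilocarpine minus non-irradiated became 2.65 points, and the lymphatic endothelial difference of the first -0.00937. With a minimum of 200 genes, the acinar difference of the second was 18.0 and the duct difference of the first 11.6. With each library clustered alone, the acinar differences were -30.4 and 17.7 and rho was -0.216. Acinar medians of the first were then -0.0012 for oxidative phosphorylation, -0.20 for granular tubule products and -0.028 for proliferation, and log2 ratios of the second were 0.19 for Klk1b21 and 0.23 for Egf. With all variable genes, rho was -0.164. At the resolution of 0.5, the acinar difference of the first was -24.7 and rho -0.173. Without dividing the irradiated + saline nuclei, rho was -0.349, and -0.481 in simulated unchanged libraries.

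TMM factors gave -0.0077 for calcium signalling and 0.093 for oxidative phosphorylation in the second comparison, where a pseudocount of 10 CPM gave 0.091 for the latter. Thinning gave 0.094 for oxidative phosphorylation in the first. Free RNA subtraction gave acinar medians of the first of 0.60 for secretory products, 0 for calcium signalling, -0.044 for oxidative phosphorylation, 0.12 for ErbB genes, 0.032 for progenitor genes and -0.14 for proliferation. In the second it gave -0.31, 0 and 0.52 for the same first 3 lists, -0.021 for the TCA cycle, -0.14 for progenitor genes and -0.16 for oxidative stress. It gave -0.023 for p53 targets in myoepithelial-like nuclei, pilocarpine against non-irradiated. Single acinar genes of the first became -1.30 (Usp18), 0.99 (Col1a2), 0.35 (Chrm3) and -0.12 (Cdkn1a), and of the second -0.14 (Pdk1), -0.070 (Aqp5), -0.16 (Atp2a2) and 0.78 (Egf). Chrm3 in duct-like nuclei became 1.59 and -0.47, and Eda2r in fibroblast-like nuclei -0.39 in the first.

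Alternatives chosen after seeing the data gave the following. With the highest doublet scores removed (890, 712 and 724 nuclei), the duct differences were 14.1 and -16.2, and the fibroblast matrix median of the second was 0.015. Cluster 11 counted as acinar-like gave -25.1 for the acinar difference of the first. Shares of named clusters alone gave -23.7 for it, and 15.1 and -17.7 for the duct differences. Equal weights of clusters 0 to 3 gave 0.11 for oxidative phosphorylation in the first, and 0.0049 for p53 targets in the second. Genes with few UMIs, such as Cdkn1a with 1 and 16, are limited by depth.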

Other observations

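Nuclei led by the submandibular gland gene Smgc, an intercalated duct marker in the list used, differed between libraries. Cluster 11 stayed unnamed because its 10 leading genes held 1 marker of another class and 0 acinar markers. Cluster 11, whose leading genes are Smgc, Xlr5a and Rnf212b and whose acinar markers stood at a median of 0.848 of their highest cluster level, held 6.03% of non-irradiated, 0.186% of irradiated + saline and 0.454% of irradiated + pilocarpine nuclei. With 1 library per group, a cluster mostly of 1 library may be that library and not a cell type, and counting it as acinar-like, chosen after seeing the data, moved the acinar share difference of irradiated + saline minus non-irradiated to -25.1 points. Mucous acinar-like nuclei, with Smgc and Muc19 among their leading genes, made up 0.367%, 0.0812% and 0.0358% of the same libraries, that is 39, 7 and 3 nuclei. Their name is weak: the 10 leading genes held 1 mucous acinar marker and 1 marker of another class. Smgc and Muc19 also overlap on the same strand of chromosome 15. Cluster 12, led by Slc9a3, Dclk1 and Wnt5b, held 1.18%, 2.76% and 3.22%, and cluster 17, led by mitotic genes such as Top2a and Tpx2, 0.198%, 0.661% and 0.430%. Cluster 7 showed acinar and granular tubule markers together and held 5.22%, 7.23% and 2.29%, with a mean doublet score of 0.173. Cluster 8 had a median of 10536 UMIs, held 2.93%, 3.16% and 3.77%, and had a mean doublet score of 0.151.

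Over all nuclei, 3 single genes chosen after seeing the data were higher in the irradiated + saline library than in the others. Fkbp5 stood at 94.7 CPM in the non-irradiated, 228 CPM in the irradiated + saline and 99.6 CPM in the irradiated + pilocarpine library, Zbtb16 at 47.0, 100.2 and 79.4 CPM, and Tsc22d3 at 94.2, 134.9 and 107.2 CPM. Glucocorticoids are known to induce each of them, and 3 chosen genes do not test that response.

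In the 3 patterns below, the tests of free RNA for the clock genes, and of free RNA and depth for the interferon response, were chosen before their results were seen, and the other tests after.

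Genes of the circadian clock differed between the non-irradiated library and both irradiated libraries. They were put in groups after seeing the data. The Arntl group held Arntl, Npas2, Clock and Nfil3, and the Per2 group held Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Ciart and Bhlhe41. Over all nuclei 4 of 4 genes of the Arntl group were lower in both irradiated libraries. Of the 10 genes of the Per2 group, 9 were higher with saline and 10 with pilocarpine. In the order non-irradiated, irradiated + saline and irradiated + pilocarpine, Arntl stood at 35.5, 5.04 and 7.10 CPM and Per2 at 18.9, 94.7 and 74.5 CPM. In the same order Clock stood at 116, 105 and 109 CPM and Nr1d1 at 83.7, 70.9 and 103 CPM. In acinar-like nuclei the median of the Per2 group minus that of the Arntl group was 2.83 on the log2 scale for irradiated + saline against non-irradiated. It was 1.96 after subtraction of free RNA, between the bounds set for and against free RNA as the source. Classes from which free RNA was taken showed the same change, at 2.53 in endothelial-like and 3.61 in fibroblast-like nuclei. Subtraction thus also removes a change shared by all classes, so a smaller value cannot point to free RNA. Glands taken at different times of day would move all classes together, but the smallest difference over 4 classes and both irradiated libraries was 0.878, short of the 1 set for this cause and above the 0.5 set against it. An effect of irradiation on the clock would give both irradiated libraries the same direction, and irradiated + pilocarpine against non-irradiated gave 2.36. Time of day and irradiation cannot be told apart, because the hour is not given and each group has 1 library, and any of the 3 may account for part of the pattern.

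The granular or striated duct-like share was highest in the irradiated + saline library. Fewer acinar-like nuclei would raise every other class alike, but the duct-like share was 3.14 times that of the non-irradiated library with a lower bound of 2.87, while the fibroblast-like share was 1.18 times with an upper bound of 1.32. Granular ducts of this gland are known to depend on sex in mice, but Xist, which differs between the sexes, stood at 1085, 1128 and 1179 CPM over all nuclei of the non-irradiated, irradiated + saline and irradiated + pilocarpine libraries, at most 1.09 times apart. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y gave from 0 to 7 UMIs each per library, so the RNA of every library was that of females. A part of the gland richer in ducts may have entered that library: ionocyte-like nuclei, which lie in ducts, had at least 1.98 times the share of each other library. The ionocyte name is weak, as the 10 leading genes held 1 ionocyte marker, Ascl3, and 1 striated duct marker, Stap1. The ionocyte-like share may therefore not be separate from the duct-like share. A part richer in ducts and a change with treatment cannot be told apart with 1 library per group.

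Interferon response genes were higher in both irradiated libraries than in the non-irradiated one. Depth was to count as a source if the median shrank when nuclei were thinned. In acinar-like nuclei the median was 0.50 at equal UMIs against 0.46 without thinning, whereas the myoepithelial-like median fell, as given above. Thinning keeps the expected composition of each nucleus. A bias tied to depth can survive it, so depth stays open. Free RNA of immune cells stays open. After subtraction the median was 0, with 12 of 24 members at 0 in both libraries and 9 of the other 12 lower. The rule that so many zeros void the test was set after seeing the value. Fibroblast-like nuclei, from which free RNA was taken, had interferon medians of 1.02 with saline and 0.84 with pilocarpine before subtraction. Subtraction thus also removes a change shared by all classes, so a lower median cannot point to free RNA. Without subtraction the smallest median over 4 classes and both irradiated libraries was 0.46, the direction an effect of irradiation needs. After subtraction the medians were 0.52 and 0.53 in fibroblast-like nuclei. As these are among the classes that define free RNA, their values are not like those of the other classes. In acinar-, duct- and myoepithelial-like nuclei they were 0 in both libraries, which shows no direction. In that order, members higher and lower were 3 and 9, 5 and 8, and 5 and 7 with saline. With pilocarpine they were 8 and 9, 7 and 3, and 12 and 8. An effect of irradiation, free RNA and any other difference between single libraries cannot be told apart.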
